A study of Mus musculus with 24 samples.

How the data were processed

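The 24 samples are mouse liver RNA recovered with polysomes, from CR and AL mice at 6 time points, with 2 libraries in each of the 12 groups of diet and time point. The deposited files hold raw read counts per gene, whole numbers with no normalization, and per the submitters' processing notes the authors used FastQC, HTSeq and DESeq2 with genome build GRCm38.p5. Versions of these tools are not given in the sources used here, and neither is an aligner. Per the labels, RNA was selected by its poly(A) tail and the libraries carry no strand. The files list 52636 genes by versioned Ensembl identifier, with 0 summary lines of HTSeq, and 52489 of them were given a symbol by the reference annotation.

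Counts were tested as deposited with edgeR 4.0.16 in R 4.3.3, using normalization by the trimmed mean of M-values (TMM) and the filterByExpr filter with the 12 groups, which left 15490 genes. All 24 libraries entered 1 model with a mean per group, so that groups of 2 libraries shared 1 estimate of the spread. The contrasts were the mean of the 6 CR groups minus the mean of the 6 AL groups, the diets at each time point, and an F-test of whether the diet difference varied with time. Rhythms were fitted with a cosine and a sine of a 24 h period per diet, tested per diet and for the difference between diets, and the amplitude is the distance from mean to peak in log2. Tests were edgeR's quasi-likelihood tests with Benjamini-Hochberg adjustment at 0.05. Of the tested genes, 1719 had at least 1 group without counts. Their averages over time points have no usable standard error, and 679 of them had p above 0.9, so changes of such genes can be missed. On the diet average 175 of them were called, and these calls are less certain. An additive model of diet and time point called 187 of them and 1783 genes in all, 1669 of them shared with the main comparison.

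The 49 gene lists (pathways, cell types and signs of RNA quality) were tested on the diet average with camera from limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01. The preset correlation does not adapt to lists whose members vary together between libraries. Camera with an estimated correlation and fry were run beside it. Genes were named by a fixed rule. A named gene needs a geometric mean of at least 10 CPM, unless it is a list member, and a symbol that is not a Gm number or Rik name. Named are the 10 higher and 10 lower genes of largest change on the diet average with the same sign at all 6 time points, up to 4 called members of smallest p per list discussed, the 3 higher and 3 lower genes of largest change at each time point, the 8 genes of smallest p for the interaction and for the rhythm difference, the clock genes, and the 5 rhythmic genes of largest amplitude per diet. Igf1, Igfbp1, Igfals and Socs2 of the growth hormone list fall outside this rule and were chosen after their values were seen. Some genes that the rule names are not reported here.

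The share of a gene's words of 50 bases that occur in annotated transcripts of other genes was computed to show reads that paralogs can share. Features that collect ribosomal RNA reads, 363 genes, were the ribosomal RNA genes of the annotation and Gm23935, Lars2, Mir6236, AY036118, Gm15564, Gm26917 and Gm42418, a set chosen after the data were seen. The total per library, 13.8 to 60.8 M counted reads (M, mega), sets the depth, and the reads outside those features were 5.64 to 59.6 M.

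Alternatives were DESeq2 1.42.0, limma-trend, size factors of the DESeq2 kind, no composition factor, no low-count filter and a stricter one of 1 CPM in 12 libraries, a 2-fold threshold, fits on part of the libraries, a replicate block, and leaving out each library. Alternatives with the ribosomal RNA ratio as a covariate, without its features, without named pairs of libraries and in the 12 libraries of lower or higher nuclear ribosomal RNA share were chosen after the data were seen. The procedures were tested on simulated counts of 14707 genes. There edgeR recovered 85 of 100 genes changed by 1 log2 unit and 100 of 100 changed by 2 on the diet average, with 14 false calls among 199, and 63 of 100 AL rhythms and 148 of 200 CR rhythms of amplitude 1. Camera called 2 of 2 changed lists and 0 of 47 unchanged ones. The simulated genes varied independently, so this does not show how often camera calls unchanged lists whose members vary together.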

Results

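Messenger RNA bound to polysomes, that is, RNA carrying several ribosomes, was sequenced from the livers of 5-month-old C57BL/6 mice. Calorie restriction (CR) began at 2 months of age, lowered calories by 30% and lasted 3 months. The comparison animals ate ad libitum (AL). Livers were taken at zeitgeber times (ZT) 2, 6, 10, 14, 18 and 22 h, which gave 12 groups of 2 libraries and 24 libraries in all. The hours at which the restricted mice were fed are not given in the sources used here. Total RNA was not analysed here, so a change in polysome-associated RNA can come from the amount of the transcript, from its loading onto polysomes, or from both. The labels number the libraries of a group without saying that they come from separate animals, and both AL libraries of ZT22 carry the number 2 (2C and 2d). The p-values therefore measure the spread between these libraries, which may be partly technical.

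Counted reads per library ranged from 13.8 to 60.8 M (M, mega), with a median of 29.5 M. The AL libraries held 26.2 ± 8.21 M and the CR libraries 33.2 ± 13.3 M (SD, n = 12 each). Features that collect ribosomal RNA took 1.02% to 62.2% of the counted reads, and the mean was 31.1 ± 21.6% in AL and 32.2 ± 21.7% in CR. The log2 ratio of these reads to all others differed by -0.06 between the diets (permutation test within time points, 100000 resamples, two-sided p = 0.954). Mitochondrial ribosomal RNA took 4.87 ± 3.17% in AL and 9.95 ± 6.46% in CR. Reads from other features numbered 5.64 to 59.6 M. Every library held between 409 and 5240 counts of the Y-linked gene Ddx3y and at most 12 counts of Xist, the RNA of the inactive X chromosome. Spearman's rho between the libraries of a group, across genes, lay between 0.919 (CR ZT10) and 0.986 (AL ZT2), and no pair differed as little as sampling noise, with chi-square per degree of freedom from 123 to 3144.

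**Figure D1:**
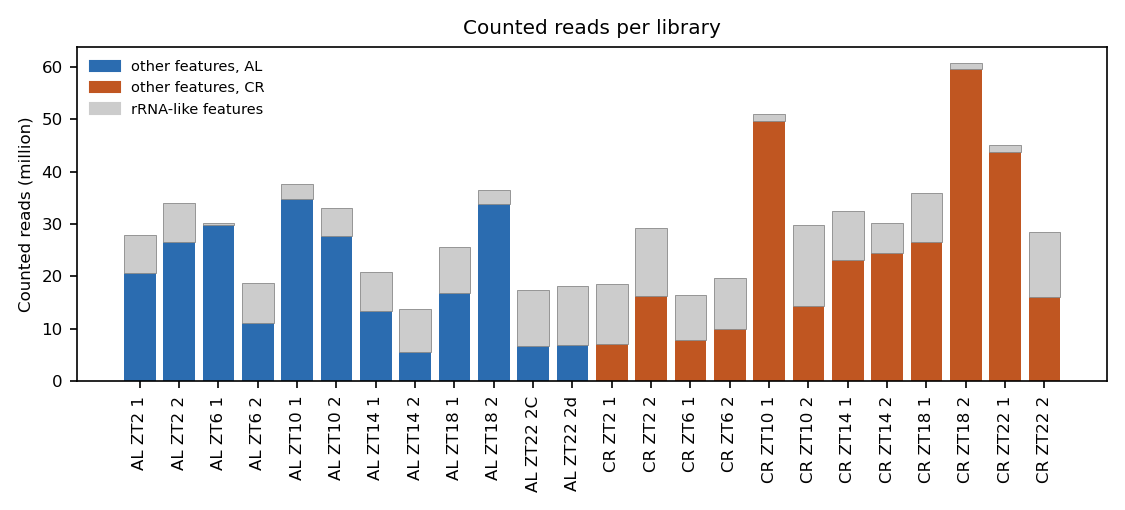
Counted reads per library (mega-reads) stacked as features other than ribosomal RNA (blue for AL, orange for CR) and features that collect ribosomal RNA (grey). Totals run from 13.8 to 60.8 M, and the grey part runs from 1.02% to 62.2% of a library without following the diet.

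The comparison of the diets averaged over the 6 time points asks what restriction changes in the polysome-associated RNA of liver at all hours. Many of its genes of largest change differ between male and female mouse liver. Cyp2b9, a cytochrome P450 of female liver, rose by 6.81 ± 0.46 log2 units (± SE), from 1.44 ± 0.843 CPM (counts scaled to library size) in AL to 155 ± 81.4 CPM in CR (SD, n = 12 each). Hsd3b5, a steroid dehydrogenase of male liver, fell by 6.06 ± 0.35, from 150 ± 75.6 to 7.89 ± 20.5 CPM, and the organic anion transporter Slco1a1 fell by 4.80 ± 0.37, from 179 ± 43.8 to 14.2 ± 25.4 CPM. Adjusted p-values by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment were 1.95e-09 for Cyp2b9, 8.67e-10 for Hsd3b5 and 7.49e-09 for Slco1a1. The genes of largest change named here were chosen among called genes with a geometric mean of at least 10 CPM and the same sign at all 6 time points. In Cyp2b9, Cyp4a14, Slco1a4, Cyp39a1, Mup7 and Slco1a1 the 12 CR libraries and the 12 AL libraries did not overlap.

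The other genes of largest rise were mostly cytochromes P450 and a transporter. Cyp4a14 and Cyp4a10, fatty acid hydroxylases under the control of PPARα, rose by 4.09 ± 0.57 and 2.75 ± 0.48 log2 units. Cyp2c40 rose by 3.75 ± 0.34, Cyp3a59 by 2.37 ± 0.22 and Cyp39a1, an oxysterol hydroxylase of bile acid synthesis, by 2.57 ± 0.18. The transporter Slco1a4 rose by 2.70 ± 0.19, Hamp2, a paralog of the iron hormone hepcidin, by 3.36 ± 0.47 and Lrtm1 by 2.37 ± 0.36. The other genes of largest fall were the major urinary proteins Mup17 (-5.75 ± 0.39), Mup7 (-5.60 ± 0.42), Mup11 (-5.40 ± 0.40), Mup14 (-5.32 ± 0.41) and Mup12 (-4.75 ± 0.40), which carry pheromones in male urine. Serpina1e, a protease inhibitor of plasma, changed by -5.48 ± 0.44, Selenbp2 by -5.31 ± 0.41 and the fatty acid hydroxylase Cyp4a12a by -5.03 ± 0.43. Adjusted p-values of these 16 genes were at most 0.000437 (Cyp4a10) by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Several of these genes have close paralogs, and the share of their 50-base words that also occurs in transcripts of other genes was 86.7% for Mup7, 85.4% for Mup12, 84.0% for Mup14, 78.1% for Mup17, 77.8% for Mup11, 60.3% for Cyp2c40, 48.9% for Cyp4a12a and 43.9% for Selenbp2, so that the value of a single member is uncertain. It was 34.6% for Serpina1e, 30.0% for Cyp3a59, 29.8% for Cyp4a10, 19.5% for Hamp2, 21.2% for Hsd3b5 and 11.2% for Cyp2b9. The reads carry no strand, and in the reference annotation of GRCm38 Hsd3b5 (ENSMUSG00000038092.6, chromosome 3, 98618634 to 98630252) overlaps Zfp697, Lrtm1 Cacna2d3, Hamp2 Gm44662, Cyp39a1 Gm25783 and Slco1a1 Gm22036, so reads in the shared stretches cannot be assigned. Cyp2b9 (ENSMUSG00000040660.6, chromosome 7, 26173411 to 26210661) overlaps no other gene.

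In total, 1960 of 15490 tested genes passed a false discovery rate of 0.05, 868 of them higher and 1092 lower in CR, by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Of these, 828 changed at least 2-fold, and 1313 (67.0%) had the same sign at all 6 time points, against 14.2% of all tested genes. Selection on the mean of the same 6 changes favours a shared sign, so this excess does not show a constant effect over the day. At least 1 group without counts occurred in 175 of the 1960, whose averages have no usable standard error. The count was 1293 without AL ZT22 2C and AL ZT10 1, the libraries with the most acute phase transcripts, and 84 in the 12 libraries with the higher share of nuclear ribosomal RNA, where 8 of the 20 genes of largest change were no longer called. Their values kept their sign there, at 3.57 for Cyp4a10, 2.85 for Hamp2, 1.87 for Lrtm1, -4.65 for Serpina1e, -3.98 for Mup7, -3.92 for Cyp4a12a, -3.67 for Mup12 and -3.63 for Mup14, with adjusted p-values from 0.0622 (Mup12) to 0.442 (Hamp2) by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The 12 libraries of higher share were fitted with the additive model, and only ZT6 and ZT22 held both diets among them. The 12 of lower share were fitted alike, and there only ZT10 and ZT18 held both diets. The count was 1170 without a composition factor. Which direction held more genes depended on the setting: higher and lower genes numbered 982 and 955 with size factors of the DESeq2 kind, 1283 and 1238 with DESeq2, 894 and 797 with a stricter filter, 895 and 849 in the 12 libraries of lower ribosomal RNA share, 830 and 762 without AL ZT10 1, and 865 and 809 without CR ZT22 2.

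Gene lists fixed before the data were examined were tested on the same average. All 25 male-biased genes fell (25 adjusted over the list alone), with a median of -3.59 log2 units, and all 23 tested female-biased genes rose (23 adjusted over the list alone), with a median of 4.92, or 4.60 with groups without counts set to the floor of 3 counts. Among the male-biased genes, C9, a component of the complement attack complex, fell by 2.22 ± 0.17 and Nudt7, a peroxisomal coenzyme A hydrolase, by 2.89 ± 0.22. Among the female-biased genes, the transcription factor Cux2 rose by 5.95 ± 0.37 and Nipal1 by 4.11 ± 0.26. Camera with a preset correlation gave an adjusted p of 6.86e-43 for the male-biased and 1.97e-38 for the female-biased list. These were the 2 lists of 49 whose calls held with an estimated correlation, at adjusted p = 0.0459 and adjusted p = 0.0292. In CR ZT6 2 and CR ZT18 2 the male-biased genes lay between the diets, with medians of -1.27 and -0.86 log2 units against the AL mean, while the other 10 CR libraries lay between -5.07 and -3.04. The female-biased genes had medians of 1.21 in CR ZT6 2 and 3.89 in CR ZT18 2.

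**Figure D2:**
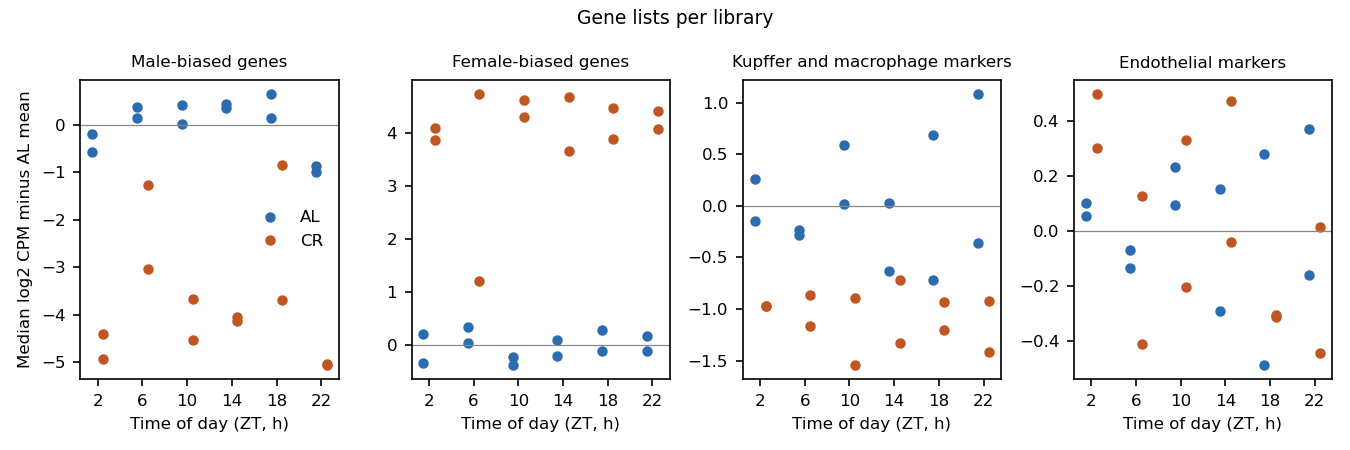
Median log2 CPM of 4 gene lists in each library, as the difference from the mean of the 12 AL libraries, against time of day (ZT, h), with AL in blue and CR in orange. Male-biased genes are at -5.07 to -0.86 in the 12 CR libraries, with CR ZT6 2 and CR ZT18 2 nearest to AL, and the endothelial markers of the diets overlap.

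Genes of the growth hormone axis, which shapes sex-biased expression in liver, moved in both directions. The growth hormone receptor Ghr fell by 0.97 ± 0.17 log2 units, Egfr by 2.51 ± 0.32 and the repressor Bcl6 by 1.44 ± 0.30, whereas Igfbp1, which binds insulin-like growth factor, rose by 1.65 ± 0.39. Igf1, the hormone that liver secretes under growth hormone, had a change of -0.07 ± 0.15 and an adjusted p of 0.840 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Of 18 members, 3 were higher and 4 lower (3 and 5 adjusted over the list alone), and the list as a whole was not called (camera, adjusted p = 0.758). Cux2, given above among the female-biased genes, is also a member and was among the 3 higher. Camera tests for a shared direction, which a list with members moving both ways cannot show. Fry's test for changes in either direction gave this list an adjusted p of 3.91e-14. That test does not set a list against other genes. It also gave 8.82e-10 for plasma proteins and 1.71e-08 for acute phase proteins, and 0.0878 for the proteasome, so passing it is not particular to this axis.

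Among genes of drug and steroid metabolism, more members passed as higher than as lower. Of 41 xenobiotic metabolism genes, 22 were higher and 4 lower (23 and 4 adjusted over the list alone), with a median of 0.64 log2 units. Cyp2a4, a steroid hydroxylase, rose by 6.50 ± 0.52 and Cyp2b13 by 6.89 ± 0.56. The camera adjusted p was 8.68e-10 with the preset correlation, and the adjusted p was 0.275 with an estimated correlation. Cyp2a4, Cyp2b13 and Cyp2b9, all among the 4 members of smallest p, are genes of higher expression in female liver.

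Some genes of glucose production and nitrogen handling passed as higher in CR. In gluconeogenesis, 6 of 13 members were higher and 0 lower (8 and 0 adjusted over the list alone), with a median of 0.45: the transaminase Got1 rose by 1.33 ± 0.18, the coactivator Ppargc1a by 1.62 ± 0.22 and the glucose 6-phosphate transporter Slc37a4 by 0.84 ± 0.13. Its camera adjusted p was 1.07e-05, and the adjusted p was 0.115 with an estimated correlation. In amino acid catabolism, 11 of 33 members were higher and 1 lower (12 and 1 adjusted over the list alone), with a median of 0.28, and Mat1a, which makes S-adenosylmethionine, rose by 1.50 ± 0.23 and the histidine lyase Hal by 0.78 ± 0.14 (camera adjusted p = 2.78e-05; adjusted p = 0.352 with an estimated correlation). In the urea cycle, 2 of 8 members were higher (3 adjusted over the list alone), with a median of 0.35: argininosuccinate lyase Asl rose by 1.16 ± 0.19 and the ornithine carrier Slc25a15 by 0.61 ± 0.14 (camera adjusted p = 0.0398; adjusted p = 0.534 with an estimated correlation). Of 18 genes of periportal hepatocytes, 9 were higher and 2 lower (12 and 2 adjusted over the list alone), with a median of 0.57. Asl and the aldehyde dehydrogenase Aldh1b1 (0.84 ± 0.16) were among the higher and Cyp2f2 (-0.98 ± 0.16) among the lower ones (camera adjusted p = 2.99e-05; adjusted p = 0.0761 with an estimated correlation). The urea cycle call was lost without AL ZT14 1 (adjusted p = 0.0523), AL ZT22 2C (0.121), CR ZT2 1 (0.0603), CR ZT10 2 (0.118), CR ZT14 2 (0.0758) or CR ZT18 1 (0.0645), by camera.

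Of the genes of fat burning and of the mitochondrial respiratory chain, a minority passed as higher. Of 34 genes of fatty acid oxidation and other PPARα targets, 11 were higher and 2 lower (11 and 2 adjusted over the list alone), with a median of 0.30. The thioesterase Acot2 rose by 2.25 ± 0.28 and Pdk4, a kinase that restrains glucose oxidation, by 1.25 ± 0.18 (camera adjusted p = 0.000932; adjusted p = 0.790 with an estimated correlation). Of 76 nuclear genes of the respiratory chain, 5 were higher (4 adjusted over the list alone), with a median of 0.19, Ndufa5 by 0.79 ± 0.20 and Atp5h by 0.64 ± 0.16 (camera adjusted p = 8.38e-05; adjusted p = 0.803 with an estimated correlation). Of 78 cytosolic ribosomal proteins, 4 were higher and 2 lower (0 and 0 adjusted over the list alone), with a median of 0.20, Fau by 0.60 ± 0.16 and Rpl8 by 0.57 ± 0.17 among the higher and Rpl10 at -0.43 ± 0.12 among the lower ones (camera adjusted p = 0.00753; adjusted p = 0.879 with an estimated correlation). The call of the ribosomal proteins was lost without AL ZT22 2C (adjusted p = 0.121), CR ZT6 2 (0.0655), CR ZT10 1 (0.491), CR ZT14 1 (0.100) or CR ZT22 1 (0.0680), by camera.

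Several genes that respond to glucocorticoids and to cold also passed as higher. Of 19 glucocorticoid-responsive genes, 4 were higher and 0 lower (6 and 0 adjusted over the list alone), with a median of 0.36. Fkbp5, a chaperone of the glucocorticoid receptor, rose by 1.90 ± 0.17, the clock gene Per1 by 1.54 ± 0.27 and metallothionein Mt1 by 1.71 ± 0.44 (camera adjusted p = 0.00442; adjusted p = 0.407 with an estimated correlation). Of 5 cold-inducible RNA-binding proteins, 3 were higher (3 adjusted over the list alone), with a median of 0.51: Cirbp rose by 1.08 ± 0.22, Rbm3 by 0.90 ± 0.18 and Hnrnpdl by 0.51 ± 0.15 (camera adjusted p = 0.0421; adjusted p = 0.481 with an estimated correlation). That call was lost without AL ZT6 1 (adjusted p = 0.0572), AL ZT14 1 (0.0677), AL ZT18 2 (0.0539), CR ZT2 1 (0.0794), CR ZT6 2 (0.0778), CR ZT10 2 (0.0779), CR ZT14 1 (0.0754), CR ZT18 1 (0.0710) or CR ZT22 2 (0.0886), by camera.

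Lower genes in CR included most markers of Kupffer cells and a minority of the genes of other immune cells, interferon response, protein folding and cell division. Of 17 markers of Kupffer cells, the resident macrophages of liver, 13 were lower and 1 higher (14 and 1 adjusted over the list alone), with a median of -1.17: Cd68 fell by 1.58 ± 0.20, lysozyme Lyz2 by 1.58 ± 0.21 and Clec4f by 1.17 ± 0.17 (camera adjusted p = 8.68e-10; adjusted p = 0.319 with an estimated correlation). Of 29 interferon-stimulated genes, 11 were lower (14 adjusted over the list alone), with a median of -0.49, and Iigp1 fell by 0.72 ± 0.13 and Oas1a by 1.27 ± 0.24 (camera adjusted p = 1.07e-05; adjusted p = 0.436 with an estimated correlation). Of 17 markers of T, B and NK cells, 3 were lower (8 adjusted over the list alone), with a median of -1.05, or -0.94 with groups without counts at the floor, and Cd4 fell by 2.47 ± 0.40 and Ighm by 1.01 ± 0.28 (camera adjusted p = 0.000608; adjusted p = 0.189 with an estimated correlation). Of 23 genes of the unfolded protein response, 7 were lower (10 adjusted over the list alone), with a median of -0.33. Sdf2l1 fell by 2.05 ± 0.20 and Xbp1, a transcription factor of that response, by 1.14 ± 0.15 (camera adjusted p = 0.000932; adjusted p = 0.522 with an estimated correlation). Of 26 cell cycle genes, 7 were lower (11 adjusted over the list alone), with a median of -0.73, and the replication helicase subunit Mcm5 fell by 1.98 ± 0.42 and Cdk1 by 1.13 ± 0.27 (camera adjusted p = 3.67e-05; adjusted p = 0.0688 with an estimated correlation).

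Markers of stellate and endothelial cells were also tested. Of 18 stellate cell and fibroblast markers, 6 were higher (6 higher and 1 lower adjusted over the list alone), with a median of 0.25: decorin, Dcn, rose by 0.87 ± 0.16 and desmin, Des, by 0.96 ± 0.24 (camera adjusted p = 0.0370; adjusted p = 0.456 with an estimated correlation). That call was lost without AL ZT2 1 (adjusted p = 0.0694), AL ZT10 2 (0.0611), AL ZT14 1 (0.0523), CR ZT2 2 (0.0510), CR ZT6 1 (0.0947), CR ZT10 2 (0.0779), CR ZT14 2 (0.0758) or CR ZT22 2 (0.0886), by camera. Among 18 endothelial markers the median was 0.00, with Lyve1 higher by 1.17 ± 0.22 and Cdh5 lower at -0.60 ± 0.17 (camera adjusted p = 0.648). In all, camera called 18 of the 49 lists. When diet labels were swapped within time points, 99 such divisions called a median of 12 lists and at most 21. Divisions that swap few libraries keep part of the diet difference, and the male-biased list still reached a camera p of 6.25e-22 among them. These counts are therefore not rates under chance alone. The p-values of the male-biased, female-biased, xenobiotic and periportal lists were smaller than in any of the 99 divisions. For the other called lists, the number of the 100 divisions, the real one included, with a p as small was 54 for ribosomal proteins, 43 for the respiratory chain, 21 for fatty acid oxidation, 21 for stellate cells, 13 for glucocorticoid-responsive genes, 11 for the urea cycle, 10 for the unfolded protein response, 10 for cold-inducible genes, 9 for interferon-stimulated genes, 6 for amino acid catabolism, 5 for T, B and NK cells, 4 for Kupffer cells, 3 for the cell cycle and 2 for gluconeogenesis.

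**Figure D3:**
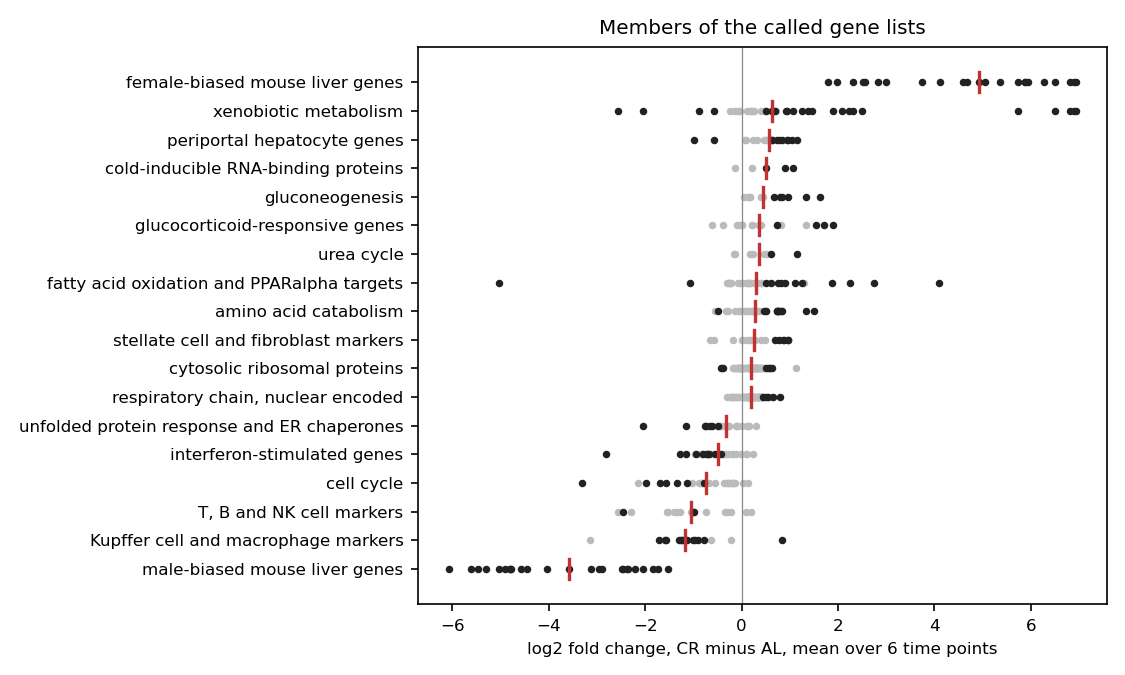
Members of the 18 gene lists called by camera, by log2 fold change of CR minus AL averaged over 6 time points, with members past a false discovery rate of 0.05 in black, the others in grey and the list median as a red bar. The medians of the male-biased (-3.59) and female-biased (4.92) genes stand apart from those of the other lists, which lie between -1.17 and 0.64.

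The diets were next compared at each time point, which asks at what hours the difference is present. Female-biased Cyp2b9 was among the 3 genes of largest rise at every time point, and a member of the major urinary proteins, Hsd3b5 or Serpina1e was among those of largest fall at each. The number of called genes was 87 at ZT2 (29 higher, 58 lower in CR), 60 at ZT6 (26 higher, 34 lower), 115 at ZT10 (46 higher, 69 lower), 264 at ZT14 (111 higher, 153 lower), 87 at ZT18 (71 higher, 16 lower) and 145 at ZT22 (58 higher, 87 lower). All of these changed at least 2-fold. Each count rests on 2 libraries against 2, with the spread shared by all 24 libraries. In simulated counts, 58% of the genes changed by 2 log2 units at ZT14 were recovered. The balance of directions turned when single libraries were left out. At ZT2 it was 10 higher and 4 lower without CR ZT2 1, and at ZT6 44 and 14 without CR ZT6 2 and 25 and 20 without AL ZT10 1. At ZT10 it was 150 and 73 without CR ZT10 1, at ZT14 37 and 9 without CR ZT14 1 and 44 and 41 without CR ZT14 2, at ZT18 14 and 18 without AL ZT18 1 and 43 and 47 without CR ZT18 2, and at ZT22 8 and 1 without CR ZT22 1.

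**Figure D4:**
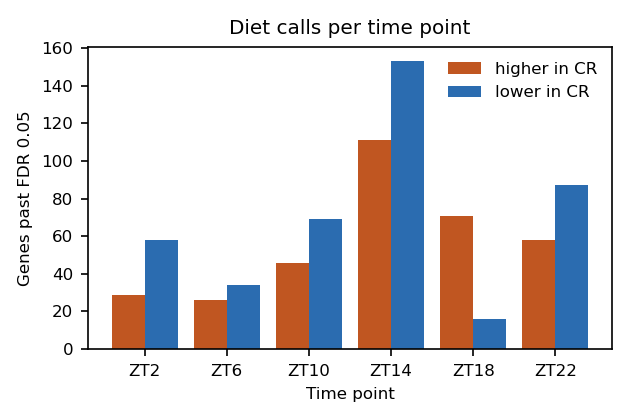
Number of genes past a false discovery rate of 0.05 at each time point, higher in CR in orange and lower in CR in blue. The lower bars are taller at 5 time points, and at ZT18, where 71 genes were higher and 16 lower, the higher bar is, but at each time point this balance turned when 1 of certain libraries was left out.

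At ZT2, Cyp2b9 rose by 7.53 ± 1.15 log2 units and Cyp3a59 by 2.52 ± 0.53. Hsd3b5 fell by 8.12 ± 0.98, and Mup12 and Cyp4a12a changed by -7.44 ± 1.15 and -7.39 ± 1.20. Adjusted p-values ran from 0.000635 (Hsd3b5) to 0.0232 (Cyp3a59) by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The count of 87 was 40 without AL ZT2 1, 36 without AL ZT2 2, 14 without CR ZT2 1, 17 without CR ZT2 2, 133 without CR ZT6 1 and 134 without CR ZT6 2. Without any single ZT2 library, Cyp3a59 had an adjusted p between 0.0897 and 0.419 by the same edgeR test, and calls also ended for Mup12 without CR ZT2 1 (0.0622) or CR ZT2 2 (0.0764) and for Cyp4a12a without CR ZT2 1 (0.0738) or CR ZT2 2 (0.0897).

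At ZT6, Fkbp5 rose by 4.10 ± 0.47 log2 units, from 3.64 ± 1.10 to 61.7 ± 28.1 CPM (SD, n = 2 each), with an adjusted p of 0.000227 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Cyp2b9 rose by 5.18 ± 1.03, and Hsd3b5 fell by 5.97 ± 0.85, Mup17 by 3.99 ± 0.87 and Nudt7 by 3.39 ± 0.55. Under other processing, the call of Cyp2b9 was lost with limma-trend (adjusted p = 0.154) and, by edgeR, with the replicate block (0.157). By edgeR it was also lost without a composition factor (0.0584), with the ribosomal RNA covariate (0.0664) and in the 4 ZT6 libraries alone (0.317). That of Mup17 was lost by edgeR without a composition factor (0.0612), with the stricter filter (0.0598) and with the covariate (0.106). Without CR ZT6 1, the change of Cyp2b9 was 0.29 (adjusted p = 0.888 by edgeR), since CR ZT6 2 held 2.86 CPM of it. This call also ended without AL ZT6 1 (adjusted p = 0.387 by edgeR) or AL ZT6 2 (0.0857), that of Mup17 without any single ZT6 library (adjusted p between 0.0603 and 0.237 by edgeR) and that of Nudt7 without AL ZT6 1 (0.207). The count of 60 was 2 without AL ZT6 1, 107 without CR ZT6 1, 94 without CR ZT10 1 and 99 without CR ZT10 2, and 7 with the ribosomal RNA ratio as a covariate.

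At ZT10, Cyp2b9 rose by 8.07 ± 1.17 log2 units and Lrtm1 by 4.71 ± 0.96, while Mup17 fell by 7.93 ± 1.04, and Mup11 and Mup7 changed by -7.71 ± 1.10 and -7.63 ± 1.13. Adjusted p-values ran from 0.000409 (Mup17) to 0.0157 (Lrtm1) by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The count of 115 was 64 without AL ZT10 1, 40 without AL ZT10 2 and 223 without CR ZT10 1. Lrtm1 was no longer called without AL ZT10 1 (adjusted p = 0.0863 by edgeR), AL ZT10 2 (0.267) or CR ZT10 1 (0.0865).

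At ZT14, Cyp4a14 rose by 6.82 ± 1.58 log2 units and Cyp2b9 by 6.50 ± 1.13, while Mup17 fell by 6.37 ± 0.97, Mup7 by 6.19 ± 1.06 and Mup14 by 6.08 ± 1.04. Adjusted p-values ran from 0.00142 (Mup17) to 0.0291 (Cyp4a14) by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The count of 264 was 95 without AL ZT14 1, 97 without AL ZT14 2, 46 without CR ZT14 1, 85 without CR ZT14 2, 424 without CR ZT10 1 and 427 without CR ZT10 2. Cyp4a14 was not called without any single ZT14 library (adjusted p between 0.0570 and 0.210 by edgeR), and calls also ended for Cyp2b9 without AL ZT14 1 (0.0729) and, without CR ZT14 1, for Mup17 (0.0503), Mup7 (0.0932) and Mup14 (0.0932).

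At ZT18, Cyp2b9 rose by 6.34 ± 1.09 log2 units and Slco1a4 by 3.03 ± 0.47. Mup7 fell by 4.80 ± 0.99, Nudt7 by 2.35 ± 0.53 and Alas2, the heme synthesis enzyme of red blood cells, by 2.39 ± 0.51. Alas2 overlaps Apex2, and the reads do not separate them. Adjusted p-values ran from 0.00375 (Slco1a4) to 0.0431 (Nudt7) by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Under other processing, edgeR lost the calls of Alas2 (adjusted p = 0.0684) and Nudt7 (0.277) without a composition factor. With the stricter filter it lost Alas2 (0.0561) and Nudt7 (0.0936), and without ZT22 Nudt7 (0.0621). The count of 87 was 32 without AL ZT18 1, 1 without AL ZT18 2 and 33 without CR ZT18 1, and without CR ZT6 2 and CR ZT18 2 it was 155, with 83 higher and 72 lower. Without AL ZT18 2, calls ended for Cyp2b9 (adjusted p = 0.209 by edgeR), Slco1a4 (0.0649), Mup7 (0.214) and Nudt7 (0.551, at -1.16 log2 units). They also ended for Slco1a4 without AL ZT18 1 (0.0625), for Mup7 (0.267) and Nudt7 (0.434) without CR ZT18 1, for Mup7 without CR ZT18 2 (0.0556) and for Alas2 without any single ZT18 library (0.0569 to 0.311). Nudt7 lay at an adjusted p of 0.0505 to 0.0550 by edgeR without AL ZT2 1, AL ZT2 2, AL ZT10 1, CR ZT2 1, CR ZT2 2, CR ZT14 1, CR ZT14 2, CR ZT22 1 or CR ZT22 2.

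At ZT22, Cyp2b9 rose by 7.25 ± 1.15 log2 units and Cyp2c40 by 5.37 ± 0.95, and Serpina1e fell by 7.40 ± 1.17, with adjusted p-values from 0.00316 (Cyp2b9) to 0.00570 (Cyp2c40) by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The acute phase genes Saa2 (-9.74 ± 2.12) and Saa1 (-8.89 ± 1.97) were called too, but AL ZT22 2C alone held 11604 CPM of Saa1 and AL ZT22 2d held 13.7 CPM. Saa1 and Saa2 share 31.5% and 30.0% of their 50-base words with other genes. Without AL ZT22 2C, the changes were -0.12 for Saa2 (adjusted p = 0.999 by edgeR) and -0.16 for Saa1 (0.994), and the calls of Cyp2b9 (0.0544) and Cyp2c40 (0.118) ended. Calls also ended without CR ZT22 1 for Saa2 (adjusted p = 0.397 by edgeR), Saa1 (0.417) and Serpina1e (0.123), and without CR ZT22 2 for Saa2 (0.117) and Saa1 (0.129). The count of 145 was 63 without AL ZT22 2C, 9 without CR ZT22 1, 74 without CR ZT22 2, 335 without CR ZT10 1 and 337 without CR ZT10 2, and 1703, of them 1637 higher, without a composition factor.

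Whether the diet difference depends on the hour was tested as an interaction. Hspb1, a small heat shock protein, had a diet difference of -1.55 log2 units at ZT6, -1.73 at ZT10 and 1.08 at ZT22 (unadjusted p = 3.77e-05, adjusted p = 0.234 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Nfil3, a repressor driven by the clock, had -2.03 at ZT6 and 0.90 at ZT14 (unadjusted p = 8.22e-05, adjusted p = 0.255 by the same edgeR test). Hsd3b5 was lower in CR at all 6 time points, from -8.12 at ZT2 to -2.15 at ZT18 (adjusted p = 0.289 by edgeR). The value at ZT18 rests on CR ZT18 2, which held 72.6 CPM against 4.79 in CR ZT18 1 and 122 and 221 in the AL libraries. The fit without CR ZT18 1, given below, keeps only that library of CR at ZT18. Slc17a4, a phosphate transporter, ran from -0.65 at ZT6 to 1.97 at ZT14 (adjusted p = 0.289 by edgeR), and Fam213b, Plekhb1 and Zfp36l1 had unadjusted p-values of 0.000141, 0.000408 and 0.000409 (edgeR). Hspb1 and Zfp36l1 share 50.1% and 54.4% of their 50-base words with other genes, and Fam213b overlaps Mmel1 and Zfp36l1 Gm26669. No gene passed: edgeR called 0 of 15490, with 1337 at an unadjusted p under 0.05, limma-trend called 0 and DESeq2 188. On simulated counts with 100 genes changed by 2 log2 units at ZT14 alone, edgeR recovered 6 and DESeq2 38, and 47 of the 112 DESeq2 calls were false, so that most differences of that size would be missed by edgeR here. The edgeR count was 41 without CR ZT6 1, 38 without CR ZT10 1, 5 without AL ZT22 2d, 2 without CR ZT6 2, 2 without CR ZT10 2 and 1 without CR ZT18 1. Calls by edgeR then included Hspb1 without CR ZT6 1 (adjusted p = 0.0374) or CR ZT10 1 (0.0483), Slc17a4 without CR ZT6 1 (0.00894), Hsd3b5 without CR ZT18 1 (0.00107), and without CR ZT10 1 Nfil3 (0.0461) and Fam213b (0.0483).

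Rhythms over 24 h were fitted in each diet to ask which polysome-associated RNAs follow the time of day. The core clock ran in both diets. Arntl, the activator of the clock, peaked at 22.63 h in AL and 23.05 h in CR with amplitudes of 2.25 and 2.14 log2 units, and its target and repressor Nr1d1 peaked at 6.78 h and 6.14 h with amplitudes of 2.66 and 2.59. The output factor Dbp peaked at 12.09 h in AL and 9.46 h in CR with amplitudes of 3.13 and 3.34. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p-values in AL and CR were 0.0109 and 0.0124 for Arntl, 0.00228 and 0.00241 for Nr1d1, and 0.000346 and 0.000247 for Dbp. Of the 20 clock genes, 11 were rhythmic in AL and 14 in CR (16 and 15 adjusted over the list alone). Npas2, Clock, Per1, Cry1, Nr1d2, Ciart and Usp2 were also called in both diets, with peaks in AL and CR at 1.31 and 23.76 h for Npas2, 1.08 and 23.75 h for Clock, 13.29 and 11.12 h for Per1, 19.90 and 19.13 h for Cry1, 9.34 and 8.88 h for Nr1d2, 11.95 and 11.19 h for Ciart and 13.69 and 13.08 h for Usp2. Over all genes, Per2, Per3 and Tef were called in CR, with adjusted p-values by edgeR of 0.00285, 0.0227 and 0.00938, against 0.135, 0.166 and 0.0643 in AL. Adjusted over the list alone, they passed in AL too, at 0.00200, 0.00377 and 0.000526 by the same edgeR test. The difference in rhythm was not called for any of them. Cry2, Hlf, Nfil3, Rora, Bhlhe40 and Bhlhe41 were called in neither diet over all genes. Adjusted over the list alone, Rora (0.0351) and Bhlhe41 (0.00557) passed in AL and Nfil3 (0.0487) in CR, by edgeR. Averaged over the day, 5 of the 20 were higher in CR and 0 lower (6 and 1 adjusted over the list alone), among them Per1 (1.54 ± 0.27), Usp2 (1.35 ± 0.27), Tef (0.61 ± 0.18), Rora (0.57 ± 0.14) and Cry2 (0.53 ± 0.15), and the list was not called (camera, adjusted p = 0.0664).

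**Figure D5:**
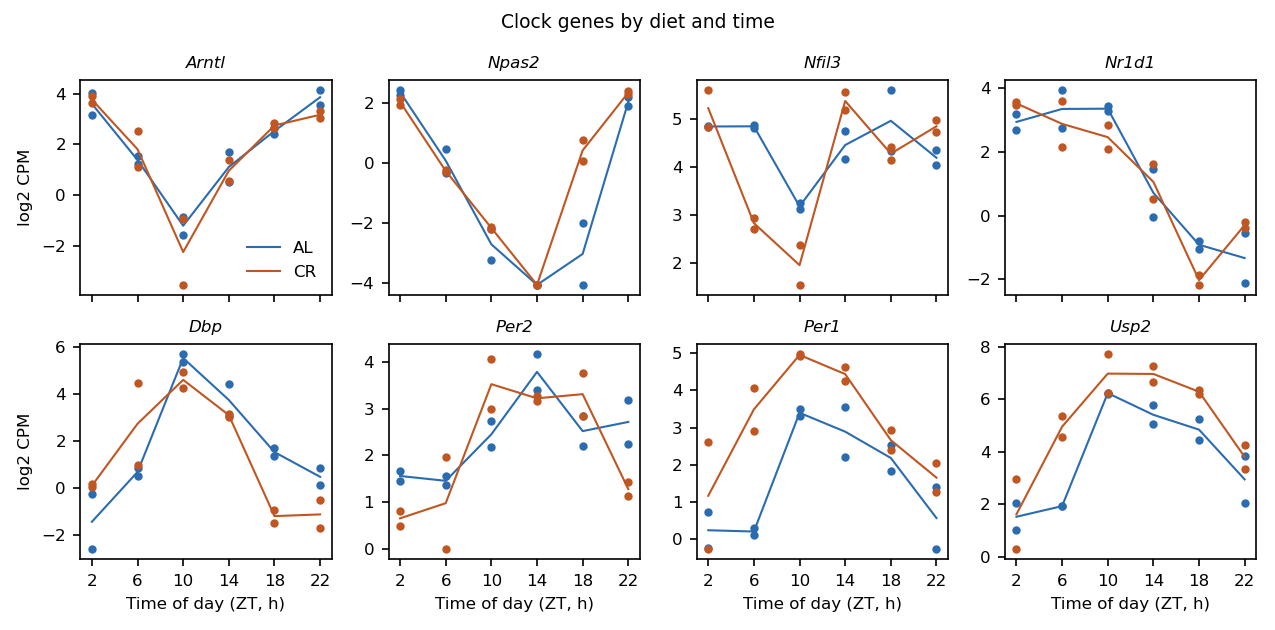
Log2 CPM of 8 clock genes in each library against time of day (ZT, h), with AL in blue, CR in orange, points for libraries and lines through the means of 2 libraries. Arntl and Npas2 are highest near ZT22 to ZT2 in both diets, the line of Nr1d1 is highest at ZT6 and ZT10 in AL and at ZT2 in CR, and the cosine fitted to Dbp, not drawn, peaks at 12.09 h in AL and 9.46 h in CR.

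Over all genes, 65 were rhythmic in AL and 301 in CR, and 41 in both, where 1.26 would be shared by independent lists (Fisher's exact test, two-sided p = 1.09e-54). Among genes with a geometric mean of at least 10 CPM, those of largest amplitude in AL were the deubiquitinase Usp2 (2.36 log2 units), the heme synthesis enzyme Alas1 (1.80, peak 13.07 h), the choline kinase Chka (1.69, peak 0.44 h), Rnf125 (1.58, peak 0.49 h) and the fatty acid elongase Elovl5 (1.51, peak 2.35 h). By the same limit they were in CR Usp2 (2.42), the phosphatidate phosphatase Lpin1 (2.04, peak 11.77 h), Angptl8, a regulator of plasma triglyceride (1.88, peak 18.69 h), the uridine phosphorylase Upp2 (1.88, peak 10.27 h) and Nr1d2 (1.86). Adjusted p-values of these genes were at most 0.00942 (Angptl8) by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Under other processing, the call of Rnf125 in AL was lost with the replicate block (adjusted p = 0.062 by edgeR). That of Alas1 was lost without a composition factor (0.0624 by edgeR) or without ZT22 (0.098). The amplitude of Angptl8 in CR was 1.57 log2 units without CR ZT6 2 and CR ZT18 2. Without strand, Angptl8 cannot be separated from Dock6 where they overlap, nor Usp2, Alas1, Chka and Upp2 from the predicted genes that overlap them. Among the 41 shared genes the peak in CR lay a median of -0.64 h from that in AL, and 30 lay within 2 h. In AL, 33 of the 65 peaks fell between 0 and 4 h, and in CR the largest number in a 4 h window was 73 between 12 and 16 h. The AL count was 41 without AL ZT2 1, 36 without AL ZT10 2 and 39 without AL ZT14 2, where Alas1 was no longer called (adjusted p = 0.0928 by edgeR), and 29 without ZT22. The CR count was 175 without CR ZT2 1, 607 without CR ZT10 2, 189 without CR ZT14 1, 154 without CR ZT14 2, 182 without CR ZT18 1 and 188 without CR ZT22 1.

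The larger count in CR does not show that rhythms differ between the diets, and the difference itself was tested. Slc17a4 had the smallest p, with an amplitude of 1.00 log2 units and a peak at 2.68 h in AL against 0.58 and 19.32 h in CR (unadjusted p = 1.86e-05, adjusted p = 0.288 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Got1 had amplitudes of 0.78 in AL and 1.13 in CR with peaks at 7.36 and 12.41 h, and Them4, Sptan1, Cdip1, Got1, the initiation factor Eif4a2 and Zfp330 had an adjusted p of 0.550 by the same edgeR test. No gene passed: edgeR called 0, with 1005 at an unadjusted p under 0.05, limma-trend 0 and DESeq2 6. Cdip1 overlaps Hmox2, Eif4a2 overlaps Rfc4 and small nucleolar RNA genes, and Sptan1 overlaps Mir6997. In simulated counts, edgeR recovered 6 of 100 genes with a rhythm of amplitude 1 in CR alone, and DESeq2 45, with 8 false calls among its 55. Without CR ZT6 1, the edgeR count was 5 and included Slc17a4 (adjusted p = 0.0133).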

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

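The tests adjusted over the clock list alone were chosen after the interaction over all genes had been seen.

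Nfil3 and Dbp differed between time points in their response to diet when the interaction was adjusted over the 20 clock genes alone, with adjusted p = 0.00164 for Nfil3 and 0.00648 for Dbp by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Over all genes the adjusted p was 0.255 for Nfil3 and 0.304 for Dbp. Dbp, an output factor of the clock, had a diet difference of 2.93 ± 0.78 log2 units at ZT6 and -2.85 ± 0.81 at ZT18. The value at ZT6 rests on CR ZT6 1, which held 22.2 CPM of Dbp against 1.93 in CR ZT6 2 and 1.76 and 1.34 in the AL libraries, and without CR ZT6 1 its list-alone p was 0.0212 by edgeR. Nfil3, which acts on the same DNA sites as a repressor, had -2.03 ± 0.40 at ZT6 and 0.90 ± 0.38 at ZT14. Leaving out any 1 of the 24 libraries kept the list-alone p of Nfil3 between 0.000138 and 0.00539 and that of Dbp between 0.0000828 and 0.0390. With the other settings the highest values were 0.00747 for Nfil3 and 0.0275 for Dbp. Npas2 and Per2 had 0.0534 each. The difference in the 24 h rhythm of Dbp had a list-alone p of 0.0991.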

How the results depend on the processing

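The alternatives that use the ribosomal RNA ratio as a covariate, remove its features, leave out the pair AL ZT22 2C and AL ZT10 1 or the pair CR ZT6 2 and CR ZT18 2, or use the 12 libraries of lower or higher nuclear ribosomal RNA share were chosen after the data were seen; all others were planned.

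No diet change of a named gene and no called list reversed its direction, while the balance of higher and lower calls turned under some settings. On the diet average, 772 values of the named genes under alternatives stayed called in the same direction. The 8 that did not all came from the 12 libraries of higher ribosomal RNA share, and the 12 of lower share kept all 20 genes. Both of these fits used the additive model of diet and time point. Only ZT6 and ZT22 held both diets among the libraries of higher share, and only ZT10 and ZT18 among those of lower share. The overlap of the diets was as small in both, so it alone does not account for 84 calls against 1744. The overlapping libraries differ, and CR ZT6 2 and AL ZT22 2C are among those of higher share. Ribosomal RNA share and these particular libraries cannot be told apart here, and the cause was not tested. With DESeq2's size factors, limma-trend, a stricter filter or the covariate the diet average count stayed within 1.5 times of 1960, and without CR ZT6 2 and CR ZT18 2 it was 1726. Counts that moved by more than 1.5 times are given here, and their cause was not tested unless stated. With the 2-fold threshold the diet average count was 828, by construction of that threshold. Without a composition factor the counts were 1170 on the diet average, 10 at ZT6, 141 at ZT14, 1703 at ZT22, 3 for the interaction, 28 for rhythm in AL and 188 in CR. That setting moved the median log2 change of all genes to -0.80 at ZT2, -0.46 at ZT6, -0.26 at ZT10, 0.27 at ZT14, 0.17 at ZT18 and 0.91 at ZT22, and the share of higher calls from 33.3% to 11.6% at ZT2, from 43.3% to 60% at ZT6, from 40% to 29.7% at ZT10, from 42.0% to 55.3% at ZT14, from 81.6% to 94.3% at ZT18 and from 40% to 96.1% at ZT22. Without a low-count filter the counts were 282 at ZT2, 439 at ZT6, 425 at ZT10, 604 at ZT14, 420 at ZT18, 562 at ZT22, 709 for the interaction, 447 and 1244 for rhythm in AL and CR, and 295 for the rhythm difference. With the stricter filter ZT18 had 33. DESeq2 called 213 at ZT2, 320 at ZT6, 341 at ZT10, 619 at ZT14, 236 at ZT18, 526 at ZT22, 188 for the interaction, 267 and 729 for rhythm in AL and CR, and 6 for the rhythm difference. Limma-trend called 137 at ZT18. With only the 4 libraries of a time point, which leaves fewer libraries to estimate the spread, the counts were 869 at ZT2, 6 at ZT6, 19 at ZT10 and 735 at ZT14. Without ZT22, rhythm counts were 29 in AL and 160 in CR. An F-test over the 6 time points in place of the cosine called 783 in AL and 1070 in CR, and the 12 CR libraries alone gave 123 rhythms. With the covariate, ZT6 had 7. Without AL ZT22 2C and AL ZT10 1 the counts were 1293 on the diet average, 68 at ZT10, 59 at ZT22 and 42 for rhythm in AL. Without CR ZT6 2 and CR ZT18 2 they were 139 at ZT2 and 155 at ZT18. In the 12 libraries of higher ribosomal RNA share the diet average count was 84, and in the 12 of lower share 1744. With an estimated correlation 2 lists were called, and fry called 18, of which 15 were shared.

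The replicate block, with the replicate number of a time point as a pair and ZT22 left out, gave 1196 on the diet average, 134 at ZT18, 15 for the interaction and, within diet, 31 for rhythm in AL. The libraries share only a number: correlations of their deviations across genes were -0.05, -0.03, 0.20, 0.03 and -0.05 at ZT2 to ZT18.

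Leaving out 1 library at a time, where a lone library is assumed to vary like the other groups, gave 1412 to 2708 genes on the diet average, 14 to 134 at ZT2, 2 to 107 at ZT6, 40 to 223 at ZT10, 46 to 427 at ZT14, 1 to 130 at ZT18, 9 to 337 at ZT22, 0 to 41 for the interaction, 36 to 96 for rhythm in AL, 154 to 607 in CR, 0 to 5 for the rhythm difference and 16 to 22 lists. Of the values of named genes under all alternatives, calls were lost in 10 of those at ZT2, 27 at ZT6, 7 at ZT10, 8 at ZT14, 30 at ZT18 and 18 at ZT22, in 4 of those for rhythm in AL and in 1 in CR. Calls were gained in 24 for the interaction and 6 for the rhythm difference, and 55 of 576 list values lost their call. Depth limits the libraries of high ribosomal RNA share most, since they hold as few as 5.64 M other reads.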

Other observations

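All tests of explanations below were chosen after the patterns had been seen, except the comparisons with other divisions of the libraries, whose number was raised after smaller runs had been seen.

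Genes of bile acid metabolism passed in both directions, and the list was not called. Cyp39a1 rose by 2.57 ± 0.18 log2 units, whereas Cyp7b1, an oxysterol hydroxylase of the alternative pathway of bile acid synthesis, fell by 2.36 ± 0.25 and Amacr, a racemase of side-chain oxidation, by 0.55 ± 0.12. Of 16 members, 3 were higher and 4 lower (4 and 4 adjusted over the list alone; camera adjusted p = 0.608). Among acute phase proteins, 5 of 27 were higher and 5 lower (5 and 6 adjusted over the list alone; camera adjusted p = 0.717), with Saa4 at -1.30 ± 0.15 and Serpina3m at 1.13 ± 0.16. Of the nutrient sensing genes 4 passed, and the list was not called: Irs2, which carries the insulin signal, rose by 1.47 ± 0.23, Insr by 0.51 ± 0.14 and Foxo1, a transcription factor that insulin inhibits, by 0.68 ± 0.13, and Eif4ebp1, a repressor of translation initiation under mTORC1, fell by 0.65 ± 0.16 (3 of 28 higher and 1 lower; 3 and 1 adjusted over the list alone; camera adjusted p = 0.750). These changes passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

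In other lists that were not called, single genes passed. Among ATF4 targets, the lipoprotein receptor Vldlr rose by 3.92 ± 0.54 log2 units and Trib3 by 1.29 ± 0.27, and asparagine synthetase Asns fell by 1.43 ± 0.37 (2 of 24 higher and 3 lower; 3 and 5 adjusted over the list alone; camera adjusted p = 0.869). Nqo1, a quinone reductase, rose by 1.45 ± 0.18 and catalase, Cat, fell by 0.50 ± 0.15 (1 of 19 NRF2 and glutathione genes higher and 1 lower, also adjusted over the list alone; camera adjusted p = 0.774). In transsulfuration, Cth, which makes cysteine, rose by 0.92 ± 0.14, with 3 of 9 higher (3 adjusted over the list alone; camera adjusted p = 0.211). In cholesterol synthesis, the sterol reductase Tm7sf2 fell by 0.62 ± 0.15 (3 of 25 higher and 1 lower; 4 and 1 adjusted over the list alone; camera adjusted p = 0.212). The pericentral list had 1 called gene of 18, Cyp1a2, which fell by 0.88 ± 0.16 (camera adjusted p = 0.750). The kinase Ulk2, of autophagy, fell by 1.14 ± 0.14 (2 of 30 higher and 1 lower; 2 and 4 adjusted over the list alone; camera adjusted p = 0.578). Median and mean differed in sign for mTORC1 (-0.03 and 0.05), NRF2 genes (-0.04 and 0.03), fatty acid synthesis (-0.05 and 0.04) and erythroid markers (0.36 and -0.30), and the camera direction for immediate early genes was up with a median of -0.03.

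The shift of sex-biased genes was weighed against 3 technical explanations. Female tissue in the CR libraries is argued against by the median change of 0.167 log2 units of Ddx3y, Uty, Kdm5d and Eif2s3y. The log2 ratio of ribosomal RNA reads differed by only -0.06 between the diets, which argues against that ratio as the source. With the ratio as a covariate 48 of 48 sex-biased genes stayed called, but so even a covariate could hardly have removed a diet difference. Mitochondrial ribosomal RNA differed more (4.87% in AL, 9.95% in CR) and was not tested as a covariate. Reads shared between paralogs are argued against by the 23 members with under 5% of shared words, all called, with a median absolute change of 2.893. A weaker growth hormone signal may take part, but Igf1, Igfals and Socs2, which that hormone raises, had a median of -0.07036, and Socs2 varied too much (± 0.35) to exclude a fall. The biological difference of diet stays open as a hypothesis whose mechanism was not tested.

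Intermediate male-biased genes in CR ZT6 2 and CR ZT18 2 could come from RNA of AL liver in these libraries. In CR ZT18 2 the apparent AL share was 0.466 from male-biased and 0.594 from female-biased genes, a difference of 0.128 within that of the other CR libraries (up to 0.622), so mixing stays open there. In CR ZT6 2 the shares were 0.329 and 0.992, a difference of 0.6629 that narrowly exceeded 0.622, which argues against mixing alone. That either was an AL liver under a CR label is argued against by the diet genes outside the sex-biased lists. On a scale where 0 is the AL mean and 1 the mean of the other CR libraries, the medians were 0.6358 in CR ZT6 2 and 0.5786 in CR ZT18 2. AL libraries reached at most 0.109 and 0.115. The lowest other CR library lay at 0.674 and 0.803, so over these genes too both libraries lay between the diets. That position does not tell mixing from other causes. A biological difference between these animals was not tested.

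The lower Kupffer cell markers may reflect fewer macrophages or less RNA per macrophage, which these data cannot separate. The endothelial median of 0.00346 shows no fall that a lower share of all cells other than hepatocytes would bring. Its standard error of 0.119 treats the 18 markers as independent. Their estimated correlation was 0.444, so that error is too small and such a fall is not excluded. The ribosomal RNA ratio as the source is argued against by its difference of only -0.06 log2 units between the diets. The 13 of 13 lower markers that stayed called with it as a covariate add little, since so even a covariate could hardly have removed a diet difference. Mitochondrial ribosomal RNA was not tested as a covariate. AL livers rich in acute phase transcripts are argued against by the median of -0.9594 without AL ZT22 2C and AL ZT10 1, where 11 of the 13 stayed called.

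Other divisions of the libraries, the real one included, show which counts chance can give. For the diet average, 1 of 40 divisions with diet labels swapped within time points called as many genes (1960 against at most 140). This is the smallest share that 40 divisions can give. Swapped groups mix the diets, so the diet difference widens their spread and can lower their counts. Divisions that swap few libraries keep part of the diet difference, which can raise their counts, and the one with 140 swapped 4 libraries. The comparison argues against chance but does not exclude it. For the lists, 10 of 100 divisions called as many (18 against at most 21), so chance is not excluded for their number. For the interaction it was 40 of 40 (0 against at most 385) and for the rhythm difference 40 of 40 (0 against at most 13). With a real count of 0 every division must call as many, so these comparisons say nothing about chance. For rhythm in AL, 1 of 100 assignments of libraries to time points called as many genes (65 against at most 8). This is the smallest share that 100 assignments can give, which argues against chance but does not exclude it. For rhythm in CR it was 5 of 100 (301 against 708, 394, 317 and 306), so chance is not excluded for that count. The assignment with 708 points to some structure of the samples. Its time points explained 0.787 of the variance of the ribosomal RNA ratio, against 0.267 in the real one, but another at 0.679 called 0 and that with 317 had 0.332, so the ratio is not shown to be that structure. With the ratio as a covariate 256 rhythms were called in CR.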
